A study of Canis lupus familiaris with 28 samples.

How the data were processed

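RNA sequencing was carried out on 28 samples of TR-T10, a dog cell line in which a tetracycline repressor controls the introduced constructs, per the labels. The line was given doxycycline-inducible shRNAs against p190A (ARHGAP35), against p190B (ARHGAP5) or against both. In experiment 1, wild-type cells and cells with the p190A shRNA, the p190B shRNA or both were harvested confluent and sub-confluent, with 2 samples in each of 8 groups. In experiment 2, all cells were confluent and each of 4 groups had 3 samples: wild type, both shRNAs, both shRNAs with YAP5SA+S94A, and a group labelled YAP5SA. YAP5SA is the transcriptional coactivator YAP1 with the serines that LATS kinases phosphorylate changed to alanine, which keeps it active, and the S94A change removes its binding to TEAD transcription factors. Per the labels' protocols, knockdown was induced for 3 days with 4 µg/ml doxycycline and cells were then replated for 3 to 5 days. The labels do not state whether wild-type cells received doxycycline. Each line went through its own selection.

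The labels disagree on whether the YAP5SA group also held the shRNAs. One field names only YAP5SA expression and another names both shRNAs. The titles of these samples lack the AB that marks the titles of groups with both shRNAs. The titles do not remove the conflict, so the group is called the libraries labelled YAP5SA throughout and the point was left open. Groups and replicate names were taken from the labels. Nothing in them says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

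Per the labels' protocols, polyA-selected libraries were made with the TruSeq mRNA kit and sequenced as single reads. The submitters' processing notes name STAR 2.3.1n, HTSeq 0.6.0 and DESeq2 1.4.5 and the dog genome build CanFam3.1, without their roles. The authors deposited 1 table per sample of whole-number counts of reads for 29884 Ensembl dog transcripts, plus 5 summary rows that name no transcript. The counts had not been normalized. A read falling on several overlapping transcripts was in the summary row for ambiguous reads, so the counts are of reads that belonged to a single transcript model. Transcripts overlapping others are therefore measured from part of their reads. Of the reads aligned to 1 place, the ambiguous row held 20.3% to 23.1% and the row for reads outside any transcript 21.2% to 23.8%. The row for alignments to several places held 24.4% to 30.7% of all counted entries. Summary rows were left out of library sizes and tests. Whether counting used strand is not given in the sources used here.

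Transcript counts summed to 10706716 to 17215544 per library in experiment 1 and 12316084 to 16786677 in experiment 2. The files of YAP5SA replicates 1 and 2 held identical values in every row, so they were counted as 1 sample, which left 27 libraries and n = 2 for that group. No other pair matched. Over transcripts with at least 20 summed counts, chi-square per degree of freedom between replicates was 10.8 to 44.8 in experiment 1 and 1.59 to 4.22 in experiment 2, above the value of 1 that counting noise alone gives. The biological coefficient of variation was 0.128 in experiment 1 and 0.0303 in experiment 2.

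The files do not pair transcript identifiers with gene names. The reference table of 43286 dog genes matched 0 of the 29884 identifiers. For that reason the targeted genes could not be read as a check of the labels, the 25 fixed gene lists were not run, and no gene is named. The rule for named items was applied without its requirement for a symbol and only to the double knockdown at confluence. Transcripts had to pass adjusted p under 0.05 in both experiments with the same sign, have a mean log2 CPM of at least 3 and have CPM values that did not overlap between the groups. They were ranked by the smaller of the 2 absolute log2 fold changes, and the first 2 in each direction are printed, of 1754 eligible that rose and 1504 that fell.

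Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Filtering used filterByExpr and scaling used TMM, followed by robust quasi-likelihood fits and F-tests with Benjamini-Hochberg adjustment. A transcript was called at adjusted p under 0.05. One fit held the 16 libraries of experiment 1 with 8 group means (12845 transcripts tested) and another the 11 distinct libraries of experiment 2 with 4 group means (13061 transcripts). The confluent wild-type and double knockdown libraries of both experiments were also fitted together with experiment as a term (12767 transcripts). The standard error of a log2 fold change was derived from the F statistic. Levels are given in CPM, transcript counts scaled to a common total of transcript-assigned reads.

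Transcript sets were carried from one experiment to the other, so that sets and tests shared no library. The 4 sets from experiment 1 were the transcripts raised or lowered by the double knockdown at confluence and those higher or lower at confluence in wild-type cells, each at adjusted p under 0.05 and at least 2-fold. They were tested in 5 comparisons of experiment 2 with camera (limma 3.58.1) on log2 CPM at a preset correlation between transcripts of 0.01, with adjustment over the 20 tests. All 20 passed at the preset correlation and 14 passed with an estimated correlation. Those 14 passed at adjusted p of 1.9e-03 to 2.9e-02 with the estimated correlation, far above their values at the preset one. The reverse family, 6 sets from experiment 2 in 7 comparisons of experiment 1, was added after the data had been seen and was adjusted over its 42 tests, of which 28 passed at the preset correlation and 11 with an estimated one. Those 11 passed at adjusted p of 1.7e-02 to 3.9e-02 with the estimated correlation. A library's score for a set is the median over its transcripts of log2 CPM minus the mean of the confluent wild-type libraries of the same experiment.

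The fits were tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed transcripts. The changed transcripts were picked among those with an expected mean count above 20. The real double knockdown comparisons called many more transcripts, so the rates below hold for the simulated changes only. For the double knockdown at confluence in experiment 1 (12595 transcripts simulated), 69.0% of 2-fold and 94.0% of 4-fold changes were recovered and 13 of 176 calls were of unchanged transcripts. For the interaction of double knockdown with density in the same simulation, 44.0% and 88.0% were recovered. For the double knockdown in experiment 2 (12824 transcripts simulated), all changes of both sizes were recovered and 8 of 208 calls were of unchanged transcripts. None of 20 random sets was called in any of the 3 simulations. Transcripts were drawn independently of each other there, so this did not test the preset correlation.

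Alternatives were DESeq2 size factors (RLE) in edgeR, no filter on low counts, DESeq2 1.42.0, limma-voom, fits to only the groups compared, leaving out each library, a replicate block, an estimated correlation and sets without a fold minimum. These, the design of each test, the gene lists and the rule for named items were fixed before the data were examined. A replicate block within density, fits without sub-confluent p190A replicate 2 for the comparisons that do not use it, and a fit with both copies of the doubled YAP5SA library were added later. No check of GC content or transcript length was made, since no annotation of these transcripts was used here.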

Results

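Messenger RNA of TR-T10 dog cells was counted in 27 distinct libraries, 16 from experiment 1 and 11 from experiment 2. Experiment 1 held 2 libraries of each of 8 groups, which crossed 4 cell types (wild type, p190A knockdown, p190B knockdown, double knockdown) with 2 densities (confluent and sub-confluent). Experiment 2 held confluent cells only, with 3 libraries each of wild type, double knockdown, and double knockdown with YAP5SA+S94A. The 3 samples labelled YAP5SA gave 2 libraries, because replicates 1 and 2 held identical values and were counted as 1 sample. Between 10706716 and 17215544 reads per library were assigned to single transcripts, and 15338 to 16264 of the 29884 transcripts had at least 1 count. Among replicate pairs, the sub-confluent p190A libraries stood apart, with a median absolute difference between replicates of 0.284 on the log2 scale against 0.154 to 0.215 in the other groups of experiment 1.

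**Figure D1:**
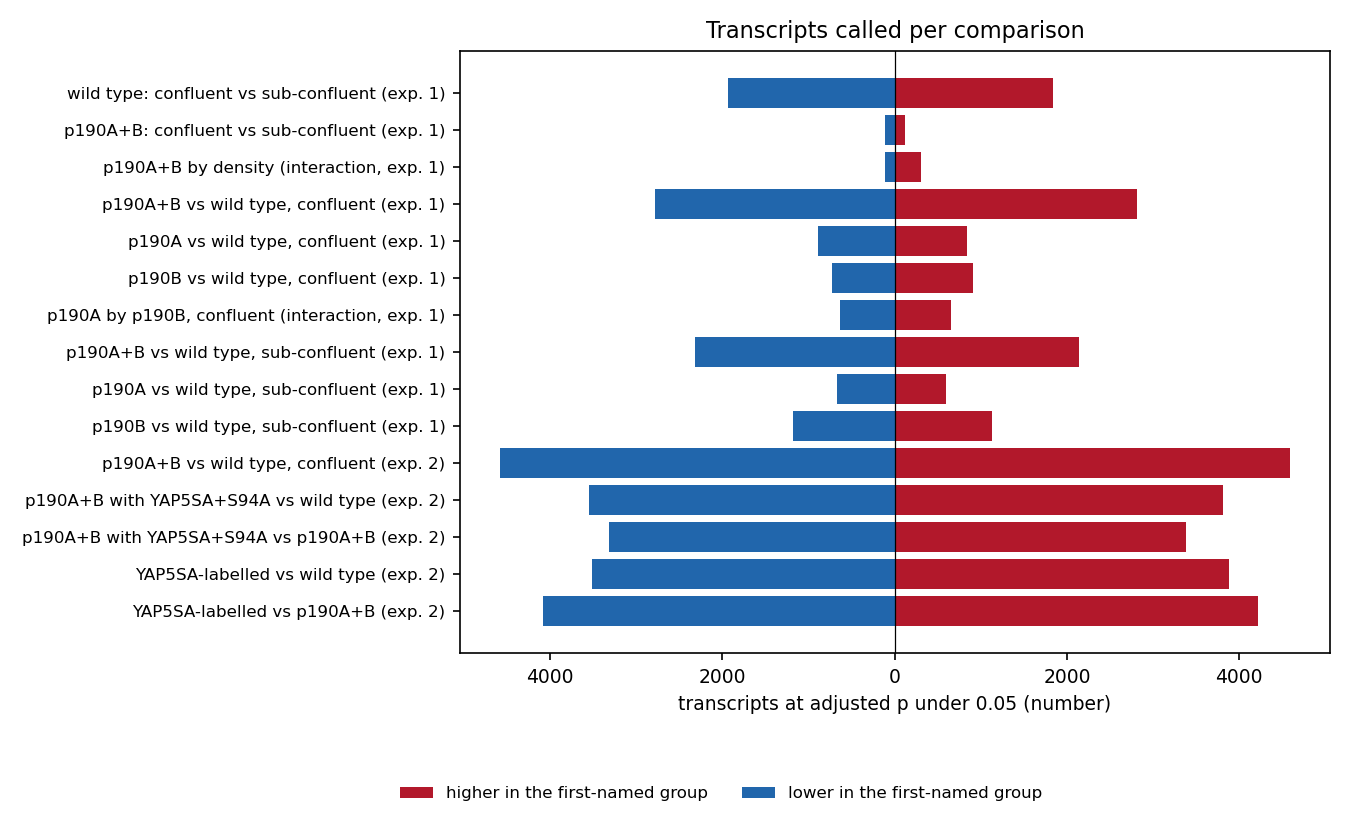
Bars give the number of transcripts called by edgeR at adjusted p under 0.05 in each of 15 comparisons, to the right those higher in the first-named group and to the left those lower (for interactions, the sign of the difference between the effects). The response to density spans 1839 higher and 1930 lower transcripts in wild-type cells and 117 higher and 115 lower in double knockdown cells.

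The first comparison asked what cell contact does to expression in wild-type cells. At confluence, 1839 transcripts were higher and 1930 lower than in sub-confluent wild-type cells, 29.3% of those tested (edgeR quasi-likelihood, adjusted p under 0.05). Of these, 780 were at least 2-fold higher and 457 at least 2-fold lower, and they are called the confluence-raised and confluence-lowered sets below. Transcript ENSCAFT00000024942 belonged to the raised set, at 112 ± 28.5 CPM (SD, n = 2) in confluent and 11.2 ± 0.786 CPM (SD, n = 2) in sub-confluent cells, a log2 fold change of 3.25 (SE 0.49, adjusted p = 8.7e-04). Transcript ENSCAFT00000022067 was in the lowered set, at 4.397 ± 0.670 CPM (SD, n = 2) in confluent and 32.4 ± 14.4 CPM (SD, n = 2) in sub-confluent cells, a log2 fold change of -2.94 (SE 0.51, adjusted p = 1.6e-03). With 2 libraries per group the count depended on each of them: it was 1918 and 1775 without confluent replicates 1 and 2, and 2323 and 1415 without sub-confluent replicates 1 and 2.

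The next comparisons asked whether loss of both p190 proteins changed that response. In double knockdown cells, 117 transcripts were higher and 115 lower at confluence, 1.81% of those tested. The confluence-raised set from wild-type cells had a median log2 fold change of 0.50 in double knockdown cells, with 21 of its 780 members called higher and 1 lower (camera adjusted p = 1.3e-13 over 2 sets; adjusted p = 2.4e-01 with an estimated correlation). The confluence-lowered set had a median of -0.27, with 35 of its 457 members called lower and 1 higher (camera adjusted p = 8.8e-11; adjusted p = 2.4e-01 with an estimated correlation). Because these sets were chosen in the wild-type libraries, the cell types were also compared on sets chosen from the single knockdown libraries, after the data had been seen. On the 441 transcripts that were at least 2-fold higher at confluence there, the median log2 response was 1.77 in wild-type and 0.72 in double knockdown cells. On the 301 that were at least 2-fold lower, it was -1.34 in wild-type and -0.43 in double knockdown cells. Tested as an interaction, the response to density differed between double knockdown and wild-type cells for 420 transcripts, 311 with a more positive and 109 with a more negative response in the double knockdown.

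Both counts moved with the processing and with single libraries. The 232 calls in double knockdown cells became 1146 without the filter on low counts, 514 with DESeq2 and 97 in a fit of only the groups compared, and the 420 interaction calls became 1213 without the filter and 701 with DESeq2. With a replicate block within density the interaction count was 1319, 835 more positive and 484 more negative. Same-numbered libraries deviated together within a density (r across transcripts 0.142 to 0.535). Among libraries, the 232 calls in double knockdown cells became 10 and 4 without confluent double knockdown replicates 1 and 2, 55 without sub-confluent replicate 2, and 742 when sub-confluent p190A replicate 2 was left out of the shared estimate of the spread. The 420 interaction calls became 118 and 77 without confluent wild-type replicates 1 and 2, 103 and 127 without sub-confluent wild-type replicates 1 and 2, 80 and 248 without confluent double knockdown replicates 1 and 2, 273 without sub-confluent double knockdown replicate 2, and 794 without sub-confluent p190A replicate 2. For the p190A knockdown, edgeR called 0 transcripts for the same interaction with density. At unadjusted p under 0.05 there were 530 of 12845, below the share of 0.05 that would pass with no effect. DESeq2 called 12, limma-voom 0, and edgeR 118 without the filter on low counts. For the p190B knockdown, edgeR and limma-voom each called 1, DESeq2 called 15, and edgeR 136 without the filter, 12 without sub-confluent p190A replicate 2, and 0 without either confluent wild-type or any of the p190B libraries or without sub-confluent wild-type replicate 2. Whether these interactions differ from that of the double knockdown was not tested.

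The double knockdown was then compared with wild type at confluence, in both experiments. In experiment 1, 2819 transcripts were higher and 2780 lower, with 812 at least 2-fold higher and 1254 at least 2-fold lower (the knockdown-raised and knockdown-lowered sets). In experiment 2, 4593 were higher and 4587 lower, with 636 and 1102 at least 2-fold, and 70.3% of the tested transcripts were called. These libraries had a narrower spread between replicates than those of experiment 1. With the 10 libraries fitted together and experiment as a term, 3725 were higher and 3826 lower.

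Transcript ENSCAFT00000029200 had the highest rank among those that rose. Its level was 1.37 ± 0.0463 CPM (SD, n = 2) in wild-type and 77.1 ± 18.7 CPM (SD, n = 2) in double knockdown cells in experiment 1, a log2 fold change of 5.83 (SE 0.84, adjusted p = 1.2e-04). In experiment 2 it was at 1.26 ± 0.244 CPM (SD, n = 3) and 59.7 ± 0.974 CPM (SD, n = 3), a log2 fold change of 5.61 (SE 0.11, adjusted p = 1.0e-46). Transcript ENSCAFT00000022067 rose by 4.86 (SE 0.51, adjusted p = 9.7e-06) and 4.11 (SE 0.20, adjusted p = 2.6e-07) on the log2 scale in experiments 1 and 2. Among those that fell, transcript ENSCAFT00000026001 went from 92.1 ± 4.09 to 1.08 ± 0.130 CPM (SD, n = 2 each) in experiment 1, a log2 fold change of -6.38 (SE 0.50, adjusted p = 1.1e-06). In experiment 2 it went from 264 ± 11.97 to 1.75 ± 0.521 CPM (SD, n = 3 each), a log2 fold change of -7.14 (SE 0.08, adjusted p = 1.0e-59). Transcript ENSCAFT00000024942, higher at confluence in wild-type cells, had log2 fold changes of -6.17 (SE 0.61, adjusted p = 6.9e-06) and -4.46 (SE 0.09, adjusted p = 1.1e-41) in experiments 1 and 2.

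The experiments share no library, so their calls could be compared directly. Of 12552 transcripts tested in both, 2172 were called higher in both and 2114 lower in both, where independent lists of these lengths would share 1007 and 963. A further 380 were called with opposite signs. Across transcripts, which are not independent replicates, the log2 fold changes of the experiments correlated with Pearson's r = 0.690 and Spearman's rho = 0.639. Of the knockdown-raised set, 653 of 781 transcripts tested in experiment 2 were higher there, with a median log2 fold change of 0.77 (camera adjusted p = 5.6e-29, and 1.9e-03 with an estimated correlation). Of the knockdown-lowered set, 1000 of 1228 were lower, with a median of -0.93 (camera adjusted p = 6.9e-31, and 2.7e-03 with an estimated correlation).

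The sets that followed confluence in wild-type cells also moved with the double knockdown in experiment 2, where all cells were confluent. Of the confluence-raised set, 527 of 759 transcripts were lower in double knockdown than in wild-type cells and 66 were higher, with a median log2 fold change of -0.64 (camera adjusted p = 3.5e-14). Of the confluence-lowered set, 304 of 441 were higher and 68 lower, with a median of 0.55 (camera adjusted p = 1.6e-11). These sets overlap the knockdown sets. Of the 759 confluence-raised transcripts, 441 were also in the knockdown-lowered set, and 240 of the confluence-lowered ones were in the knockdown-raised set. Both kinds of set were chosen against the same confluent wild-type libraries of experiment 1, so these are not separate results.

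The single knockdowns at confluence asked how much each protein contributed. The p190A knockdown raised 836 and lowered 892 transcripts, and the p190B knockdown raised 904 and lowered 725. Sets chosen in experiment 2 were followed in these libraries, a test added after the data had been seen. Only members also tested in experiment 1 could be followed, 601 of 636 raised and 940 of 1102 lowered transcripts. The 601 transcripts raised at least 2-fold by the double knockdown in experiment 2 had median log2 fold changes of 0.41 with the p190A shRNA (camera adjusted p = 4.5e-15), 0.38 with the p190B shRNA (camera adjusted p = 3.3e-13) and 1.03 with both (camera adjusted p = 1.0e-23). With an estimated correlation these camera adjusted p were 3.1e-02, 3.2e-02 and 1.7e-02. The 940 lowered transcripts had medians of -0.70 with the p190A shRNA (camera adjusted p = 5.5e-25, and 5.8e-02 with an estimated correlation), -0.50 with the p190B shRNA (camera adjusted p = 1.4e-15, and 1.3e-01 with an estimated correlation) and -1.50 with both (camera adjusted p = 1.8e-37, and 3.2e-02 with an estimated correlation).

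Transcript ENSCAFT00000026001 was lowered by either knockdown alone, to 6.14 ± 0.822 CPM (SD, n = 2) with the p190A shRNA (log2 fold change -3.88, SE 0.41, adjusted p = 4.9e-05) and 2.71 ± 1.26 CPM (SD, n = 2) with the p190B shRNA (log2 fold change -5.03, SE 0.45, adjusted p = 9.5e-06). Transcript ENSCAFT00000022067 rose to 35.0 ± 9.09 CPM (SD, n = 2) with the p190A shRNA, from 4.397 ± 0.670 CPM (SD, n = 2) in wild type (log2 fold change 3.00, SE 0.51, adjusted p = 1.5e-03). With the p190B shRNA its log2 fold change was 1.65 (SE 0.53, adjusted p = 6.0e-02). That change was called with DESeq2 (adjusted p = 2.0e-02), in a fit of only the groups compared (adjusted p = 1.3e-03) and without the filter on low counts (adjusted p = 3.2e-16). In the last 2 fits the log2 fold change was nearly the same (1.643 and 1.649). Their smaller p-values rest on another estimate of the spread and show no larger effect. It was also called with a replicate block (adjusted p = 5.4e-03) and with a replicate block within density (adjusted p = 9.5e-03). RLE size factors (adjusted p = 6.2e-02) and limma-voom (adjusted p = 2.2e-01) did not call it. Transcript ENSCAFT00000029200 was not called with either shRNA alone, with log2 fold changes of 2.00 (SE 0.99, adjusted p = 2.2e-01) for p190A and -0.40 (SE 1.31, adjusted p = 9.0e-01) for p190B. The p190A change was called in a fit of only the groups compared (adjusted p = 9.0e-04) and without the filter (adjusted p = 2.6e-11). Its log2 fold change was again nearly the same there (1.992 and 2.012). Transcript ENSCAFT00000024942 had log2 fold changes of -2.15 (SE 0.46, adjusted p = 7.2e-03) with the p190A shRNA and -1.53 (SE 0.445, adjusted p = 3.6e-02) with the p190B shRNA. The p190A call was lost without wild-type replicate 2 (adjusted p = 6.9e-02) and without p190A replicates 1 and 2 (adjusted p = 7.8e-02 and 6.3e-02). The p190B call was lost with DESeq2 (adjusted p = 1.2e-01) and with a replicate block within density (adjusted p = 7.4e-02). Leaving out wild-type replicates 1 and 2 in turn gave p190B log2 fold changes of -1.765 and -1.269. Leaving out p190B replicates 1 and 2 in turn gave -1.406 and -1.683. The p190B call was lost in each of these fits too. Every fit without a library, for p190A and p190B, kept a lone library in a compared group.

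**Figure D2:**
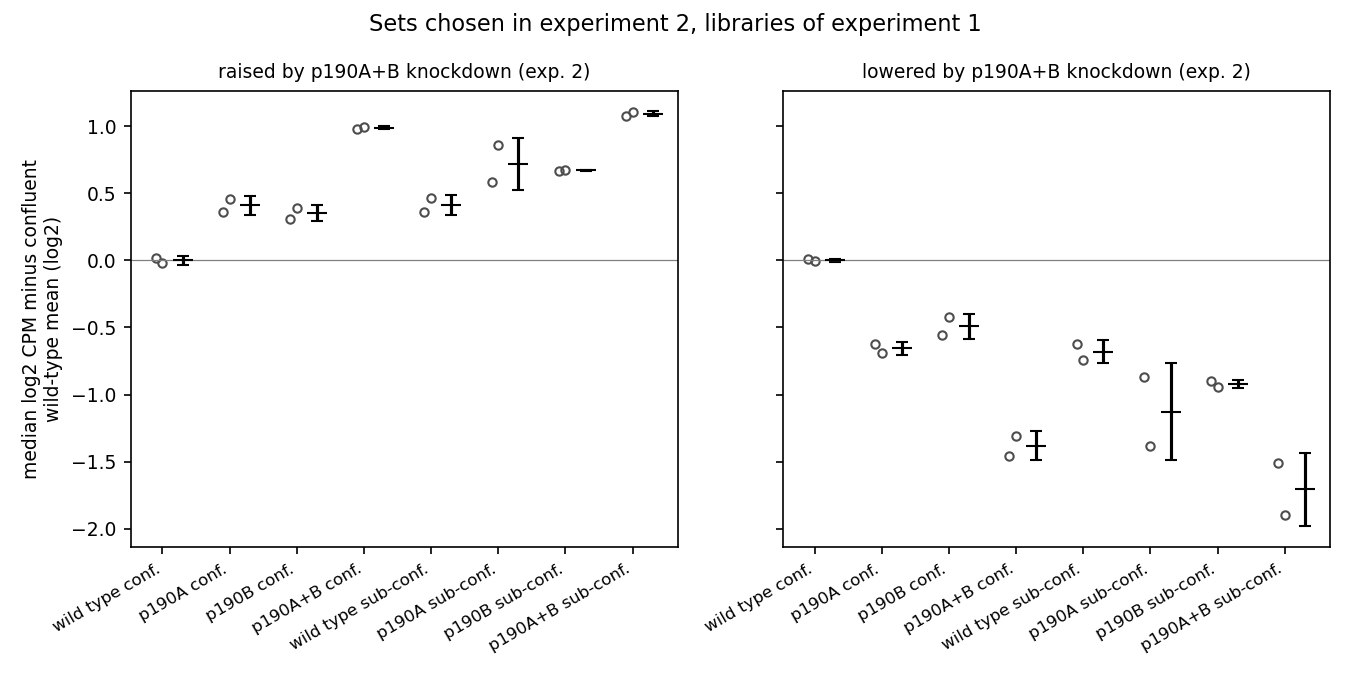
Each circle is 1 library of experiment 1 and gives the median over a transcript set of log2 CPM minus the mean of confluent wild-type libraries; bars give the mean and SD (n = 2). The left panel shows the 601 transcripts raised at least 2-fold by the double knockdown in experiment 2 and also tested in experiment 1. The right panel shows the 940 lowered ones. At confluence, the double knockdown libraries have mean scores of 0.99 and -1.38.

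Whether the knockdowns combined additively on the log2 scale was tested as an interaction at confluence. The double knockdown differed from the sum of the single ones for 1293 transcripts, 653 above and 640 below the sum. The sets chosen in experiment 2 had median interaction terms of 0.07 for the 601 raised transcripts (camera adjusted p = 6.1e-01) and -0.31 for the 940 lowered ones (camera adjusted p = 1.1e-01), so no departure of either set from the sum passed the test.

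In these comparisons every library of a compared group moved the count by over 1.5 times, as leaving it out left a lone library assumed to vary like the other groups. Without wild-type replicates 1 and 2, the p190A count of 1728 became 886 and 710, and without p190A replicates 1 and 2 it became 810 and 737. In a fit of only the groups compared the p190A count rose to 2650. With a replicate block within density the p190A, p190B and interaction counts rose to 2724, 2511 and 2601. The p190B count of 1629 became 885 and 814 without the wild-type replicates and 830 and 1018 without p190B replicates 1 and 2. The interaction count became 717 and 712 without wild-type replicates 1 and 2, 615 and 786 without those of p190A, 857 and 786 without those of p190B, and 659 and 816 without those of the double knockdown, and rose to 2004 without the filter on low counts and 2374 in a fit of only the groups compared.

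In sub-confluent cells, the double knockdown raised 2146 and lowered 2321 transcripts against sub-confluent wild type, the p190A knockdown raised 599 and lowered 664, and the p190B knockdown raised 1131 and lowered 1185. The 601 transcripts raised by the double knockdown in experiment 2 had a median log2 fold change of 0.70 between sub-confluent double knockdown and wild-type cells (camera adjusted p = 8.2e-17), and the 940 lowered ones a median of -1.16 (camera adjusted p = 4.7e-26; adjusted p = 5.6e-02 with an estimated correlation). Transcript ENSCAFT00000022067 reached 392 ± 90.1 CPM (SD, n = 2) in sub-confluent double knockdown cells, a log2 fold change of 3.56 over wild type (SE 0.43, adjusted p = 3.7e-05). Transcript ENSCAFT00000026001 fell to 0.492 ± 0.367 CPM (SD, n = 2), from 4 and 10 counts in the libraries, a log2 fold change of -5.28 (SE 0.57, adjusted p = 1.5e-05). The double knockdown count of 4467 became 2874 without wild-type replicate 1 and 2740 without double knockdown replicate 2. In the p190A comparison, whose replicates differed most, the count of 1263 became 538 and 505 without wild-type replicates 1 and 2, and 228 in a fit of only the groups compared, with 59 raised and 169 lowered. The p190B count of 2316 became 1309 and 1100 without these and 996 and 1273 without p190B replicates 1 and 2.

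The S94A libraries, from double knockdown cells that also expressed YAP5SA+S94A, asked what a YAP that cannot bind TEAD does to the knockdown response. Against double knockdown cells, 3381 transcripts were higher and 3313 lower, with 339 and 247 at least 2-fold. The knockdown-raised set from experiment 1 was lower in the S94A libraries, with 529 of 781 transcripts called lower and 64 higher and a median log2 fold change of -0.42 (camera adjusted p = 3.5e-21). The knockdown-lowered set was higher, with 670 of 1228 called higher and 106 lower and a median of 0.38 (camera adjusted p = 1.0e-14). Against wild type, 3807 transcripts were higher and 3554 lower in the S94A libraries. The knockdown-raised set kept a median of 0.43 over wild type (camera adjusted p = 4.3e-19) and the knockdown-lowered set one of -0.51 (camera adjusted p = 1.6e-22), so the S94A libraries lay between wild type and double knockdown. As library scores, the raised set was at 0.76 ± 0.04 in double knockdown and 0.43 ± 0.01 in S94A libraries (SD, n = 3 each), and the lowered set at -0.91 ± 0.04 and -0.50 ± 0.01 (SD, n = 3 each). No group held both shRNAs with a control construct. A weaker knockdown or the separate selection of the S94A line therefore cannot be told apart from an effect of YAP5SA+S94A.

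Of the confluence-raised set, 274 of 759 transcripts were higher and 106 lower in S94A than in double knockdown libraries, with a median log2 fold change of 0.16 (camera adjusted p = 2.4e-03; adjusted p = 2.1e-01 with an estimated correlation). Of the confluence-lowered set, 238 of 441 were lower and 96 higher, with a median of -0.26 (camera adjusted p = 3.0e-05; adjusted p = 9.5e-02 with an estimated correlation). Transcript ENSCAFT00000029200 was at 14.3 ± 0.650 CPM (SD, n = 3) in the S94A libraries, a log2 fold change of -2.03 from the double knockdown (SE 0.07, adjusted p = 2.2e-34). Transcript ENSCAFT00000026001 was at 7.91 ± 0.419 CPM (SD, n = 3), a log2 fold change of 2.17 from the double knockdown (SE 0.16, adjusted p = 1.8e-18).

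**Figure D3:**
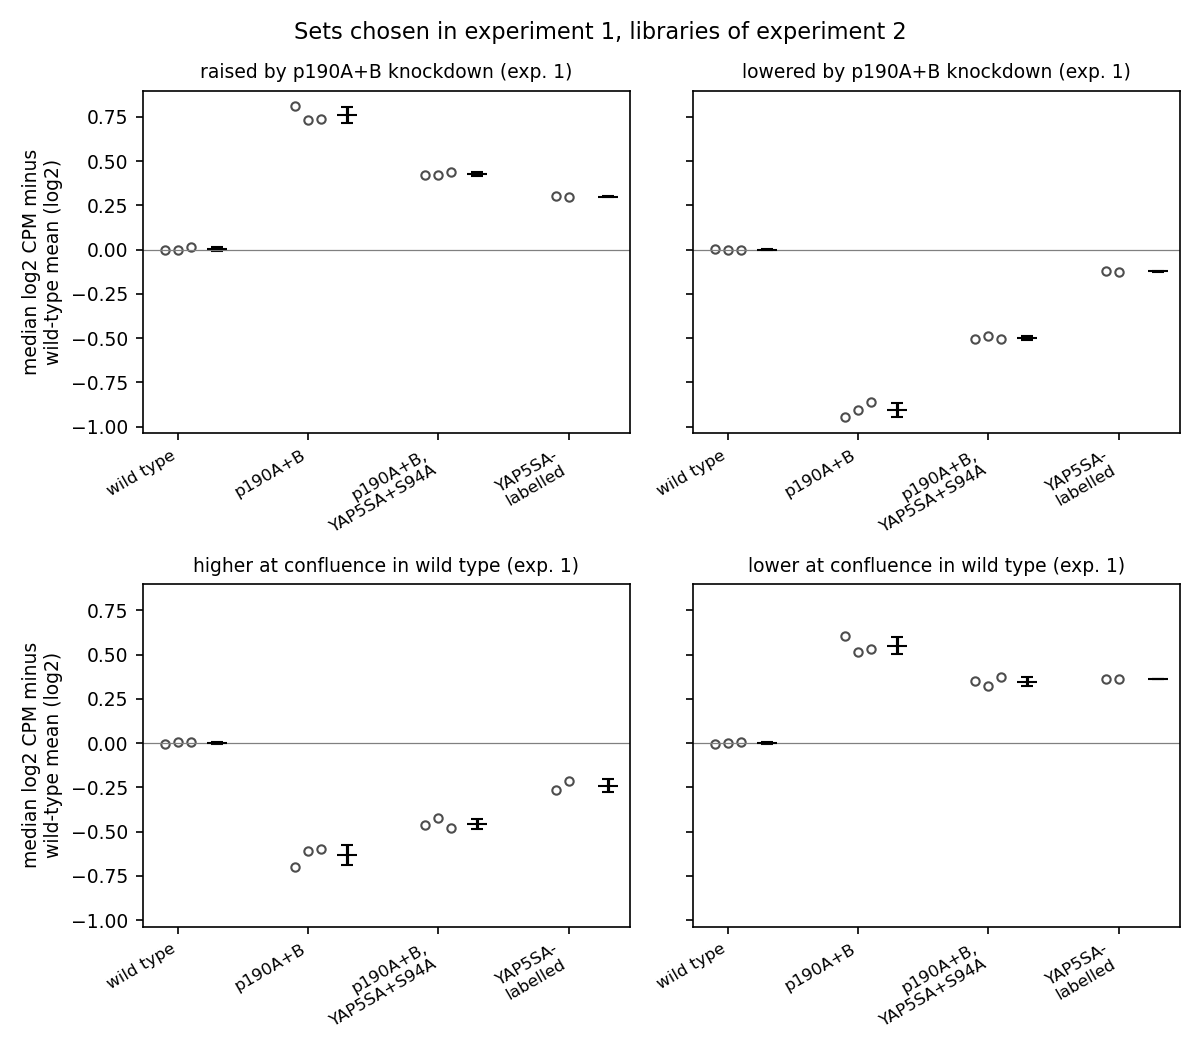
Each circle is 1 library of experiment 2 and gives the median over a transcript set from experiment 1 of log2 CPM minus the wild-type mean; bars give the mean and SD (n = 3, and n = 2 for the libraries labelled YAP5SA). For the set lowered by the double knockdown, the mean is -0.91 in double knockdown libraries, -0.50 in S94A libraries and -0.12 in libraries labelled YAP5SA.

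The libraries labelled YAP5SA asked what an active YAP does at confluence; the labels disagree on whether their cells also held the shRNAs. Against wild type, 3884 transcripts were higher and 3514 lower, with 576 and 405 at least 2-fold. Of the confluence-lowered set, 266 of 441 transcripts were higher and 56 lower, with a median log2 fold change of 0.36 (camera adjusted p = 1.8e-09). Of the confluence-raised set, 334 of 759 were lower and 132 higher, with a median of -0.26 (camera adjusted p = 1.3e-04; adjusted p = 1.3e-01 with an estimated correlation). Of the knockdown-raised set, 420 of 781 were higher and 117 lower, with a median of 0.31 (camera adjusted p = 2.6e-08). Of the knockdown-lowered set, 471 of 1228 were lower and 317 higher, with a median of -0.12 (camera adjusted p = 3.2e-02; adjusted p = 3.1e-01 with an estimated correlation).

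Against double knockdown cells, 4222 transcripts were higher and 4084 lower in the libraries labelled YAP5SA, with 1112 and 511 at least 2-fold. The knockdown-lowered set was higher than in the double knockdown, with a median log2 fold change of 0.81 and 880 of 1228 called higher (camera adjusted p = 4.7e-24), and the knockdown-raised set was lower, with a median of -0.48 and 523 of 781 called lower (camera adjusted p = 1.3e-15). The confluence-raised set had a median of 0.40 (camera adjusted p = 5.6e-07; adjusted p = 6.6e-02 with an estimated correlation) and the confluence-lowered set one of -0.18 (camera adjusted p = 9.9e-03; adjusted p = 2.5e-01 with an estimated correlation). The 4 printed transcripts differed in these libraries. Transcript ENSCAFT00000026001 was at 197 ± 1.03 CPM (SD, n = 2), a log2 fold change of -0.34 from wild type (SE 0.04, adjusted p = 2.0e-10) and 6.80 from the double knockdown (SE 0.08, adjusted p = 7.0e-57). Transcript ENSCAFT00000024942 was at 100.2 ± 9.50 CPM (SD, n = 2), above the wild-type level of 68.5 ± 2.88 CPM (SD, n = 3) by a log2 fold change of 0.62 (SE 0.06, adjusted p = 6.5e-14). Transcripts ENSCAFT00000029200 and ENSCAFT00000022067 were both above wild type, by log2 fold changes of 2.08 (SE 0.20, adjusted p = 3.2e-13) and 2.29 (SE 0.28, adjusted p = 1.6e-04), and both below the double knockdown, by log2 fold changes of -3.54 (SE 0.09, adjusted p = 3.5e-39) and -1.81 (SE 0.17, adjusted p = 2.8e-05).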

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

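The comparison of libraries labelled YAP5SA with S94A libraries and the tests of the effect sizes in the 2 experiments, of splits within each experiment, and of the interactions with experiment and of each single knockdown with density were chosen after the results had been seen.

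The response to density differed between double knockdown and wild-type cells for 420 transcripts (edgeR interaction). In the sets chosen from single knockdown libraries the response of the double knockdown was 0.324 and 0.406 times that of wild type, and between 0.224 and 0.498 times without any one of the 8 libraries, which argues against a pick of large values in the wild-type libraries. A wider spread between double knockdown replicates, 1.02 times that of wild type at confluence and 1.25 times in sub-confluent cells, does not shrink a median of fold changes, and the ratio of 0.324 argues against it as the cause. No single confluent double knockdown library carried the difference, since the ratio reached at most 0.475 without either. The densities that the cultures reached, the extent of knockdown and the separate selection of the lines were not tested and stay open beside an effect of p190 itself, which may be a biological explanation.

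The effect of the double knockdown at confluence differed between the experiments for 4620 transcripts (edgeR interaction over the 10 libraries). That fit used a shared estimate of the spread, although the biological coefficient of variation was 0.128 in experiment 1 and 0.0303 in experiment 2. Its median standard error was 0.155, below the 0.187 of the same comparison in experiment 1 alone, so the count may be too high. No alternative fit was run for it. In sets chosen from the sub-confluent libraries of experiment 1 the median log2 fold change was 1.15 in experiment 1 and 0.74 in experiment 2 for 526 raised transcripts, and -1.52 and -0.88 for 961 lowered ones, but that choice was also made within experiment 1. In sets chosen in experiment 2 the excess in experiment 1 was -0.314 for raised transcripts (-0.356 to -0.260 without any one library) and 0.0311 for lowered ones (-0.0412 to 0.124), so a larger effect in experiment 1 and the choice of transcripts cannot be told apart in either direction. Over 8703 transcripts chosen by abundance and not by fold change, the standard deviation of the log2 fold change net of error was 0.746 in experiment 1 (0.709 to 0.784 without any one library) and 0.633 in experiment 2 (0.629 to 0.637), a wider spread in experiment 1 that does not separate the directions. Days in culture, density and extent of knockdown, which could differ between the experiments, were not tested.

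The knockdown-lowered set was hardly lowered in the libraries labelled YAP5SA, where the lowest library lay 0.362 above the highest S94A library on the log2 scale, against a range of 0.0184 among S94A libraries. No explanation was tested, and this could not settle the conflict between the labels, since cells without the shRNAs, an offset by YAP5SA and a weaker knockdown would give the same values.

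The p190A effect at confluence depended on the p190B shRNA for 1293 transcripts (edgeR interaction), for 615 to 857 without any one of the 8 libraries compared, for 2004 without the filter on low counts and for 2374 in a fit of only the groups compared. The p190B effect depended on density for 1 transcript, against 809 at unadjusted p under 0.05, 136 without the filter on low counts, 15 with DESeq2, 17 in a fit of only the groups compared, 12 without sub-confluent p190A replicate 2 and 0 without 7 of the 8 libraries compared, each left out alone. Alignments to several places, which entered no comparison, made up a higher share in every library of 5 groups than in any confluent wild-type library of the same experiment (26.3% and 25.7% on average in experiments 1 and 2). The mean share was 28.2% in confluent and 29.8% in sub-confluent double knockdown cells, 28.7% in sub-confluent wild-type cells and 27.1% in sub-confluent p190B cells of experiment 1, and 27.4% in double knockdown cells of experiment 2. Sub-confluent p190A cells had 26.5% and 28.9% in their 2 libraries, the first just under the highest confluent wild-type library (26.6%).

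For the 3 comparisons of experiment 2 with 3 libraries a side, the 10 possible splits are too few for a share under 0.05. The real splits gave 9180 calls for double knockdown against wild type, 6694 for S94A against double knockdown and 7361 for S94A against wild type, and the highest of the other splits gave 0 in each case. Over both experiments, 1 of 100 splits drawn from 126, the real one with 7551 calls, gave as many, and the highest of the others gave 283. Of the 60 splits that exchange libraries only within an experiment, 1, the real one, gave as many, and the highest other again gave 283. The other splits mix wild-type and double knockdown libraries, and none separates the knockdown from the separate selection of the lines. The count followed the real grouping, but these splits cannot tell its source.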

How the results depend on the processing

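The tests with a replicate block within density, without sub-confluent p190A replicate 2 where a comparison does not use it, with both copies of the doubled YAP5SA library, of each single knockdown by density, and with RLE or a replicate block for the sets were chosen after the data had been seen. RLE size factors and limma-voom moved no count of calls by over 1.5 times, and counts of experiment 2, of both experiments together and of calls shared between experiments stayed within 1.5 times under each alternative run. The set tests of experiment 2 kept their direction with RLE, no fold minimum and an estimated correlation, and so did the 12 of 20 rerun with a replicate block, which left out those of YAP5SA; no log2 fold change of the 4 printed transcripts reversed in the comparisons rerun. Without the filter on low counts, calls for density in double knockdown cells, its interaction and the p190A by p190B interaction were 1146, 1213 and 2004, and with DESeq2 the first 2 were 514 and 701. Fitting only the groups compared gave 97 for density in the double knockdown, 2650 for p190A and 2374 for the p190A by p190B interaction at confluence, and 228 for sub-confluent p190A. The cause of these moves was not tested. Leaving out 1 library gave 1415 to 4379 calls for density in wild-type cells, 4 to 742 for density in double knockdown cells, 77 to 794 for their interaction, 710 to 2169 for p190A, 814 to 1939 for p190B and 615 to 1929 for their interaction at confluence, and 2740 to 5006 for the double knockdown, 505 to 1368 for p190A and 996 to 2898 for p190B in sub-confluent cells. The lower ends have fewer libraries in the groups compared, and the upper ends are all without sub-confluent p190A replicate 2.

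Replicates share only a number in experiment 1. Same-numbered libraries deviated together within a density (r across transcripts 0.142 to 0.535) and not between densities (-0.198 to 0.0254), and the letters of experiment 2 showed no pairing (-0.0348 to 0.0189). The replicate block by number moved density in double knockdown cells to 354 calls, the p190B by density interaction from 1 to 2 and no other count by over 1.5 times; with it, the double knockdown at confluence had 5926 and 9118 calls in experiments 1 and 2. The replicate block within density, which cannot be separated from a comparison of densities and was not run for those, gave 1319 calls for the double knockdown by density interaction, 17 and 13 for those of p190A and p190B, 2724, 2511 and 2601 for p190A, p190B and their interaction at confluence, and 2225 and 3570 for sub-confluent p190A and p190B.

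With an estimated correlation 6 of the 20 set tests of experiment 2 no longer passed: confluence-raised and confluence-lowered sets in S94A against double knockdown (adjusted p = 2.1e-01 and 9.5e-02) and in YAP5SA against double knockdown (6.6e-02 and 2.5e-01), and the knockdown-lowered and confluence-raised sets in YAP5SA against wild type (3.1e-01 and 1.3e-01). The alternatives for the 25 gene lists (estimated correlation, fry, RLE, replicate block) were not run, since no identifier matched a gene name. Depth limits the 2-library groups of experiment 1 less than the spread between replicates does, and YAP5SA comparisons rest on 2 libraries.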

Other observations

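The test of S94A libraries by density response, the sets chosen in experiment 2, the use of single double knockdown libraries as reference and the turned reading of the YAP5SA shares were chosen after the results had been seen; the test of YAP5SA libraries by density response was set down before its result.

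Transcripts changed at least 2-fold between S94A and double knockdown libraries in experiment 2 had medians of the opposite sign under knockdown in experiment 1, with exceptions in both directions. Double knockdown cells enter these comparisons on opposite sides. A shift particular to that line, present in both experiments, would give the same signs without YAP5SA+S94A. Of 339 transcripts raised at least 2-fold in S94A libraries, 297 were also tested in experiment 1. Their median log2 fold change in double knockdown against wild-type cells was -1.67 at confluence (203 called lower, 10 higher, camera adjusted p = 7.1e-24). In sub-confluent cells these 297 had a median of -1.83 (204 lower, 4 higher, camera adjusted p = 9.1e-31). Their median response to confluence in wild-type cells was 0.15 (70 higher, 54 lower, camera adjusted p = 3.1e-01). Of 247 lowered in S94A libraries, 217 were also tested in experiment 1. These had medians of 1.15 at confluence (110 called higher, 25 lower and 82 not called, camera adjusted p = 3.2e-08) and 0.95 in sub-confluent cells (112 higher, 24 lower, camera adjusted p = 9.1e-10).

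Sets were also chosen from the libraries labelled YAP5SA. Of 576 raised at least 2-fold over wild type, 490 were also tested in experiment 1. These had a median of 0.06 in double knockdown against wild-type cells at confluence there, with 148 called higher and 125 lower (camera adjusted p = 4.8e-01). Their median response to confluence in wild-type cells was -0.24 (71 higher, 123 lower, camera adjusted p = 3.4e-02, and 1.3e-01 with an estimated correlation). Of 405 lowered ones, 354 were also tested in experiment 1. These had a median of -0.74 in the double knockdown at confluence, with 146 lower and 40 higher (camera adjusted p = 4.9e-06, and 1.7e-01 with an estimated correlation). Their median response to confluence in wild-type cells was 0.56 (camera adjusted p = 5.8e-06, and 1.7e-01 with an estimated correlation).

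One hypothesis was that the part of the knockdown response that also follows density is moved more by YAP5SA than the part that does not. The knockdown sets of experiment 1 were divided into transcripts that responded to density in wild-type cells at least 2-fold in the opposite direction and transcripts that did not (adjusted p of 0.05 or more and a log2 response under 0.5). In experiment 2, the YAP5SA score was 52.6% of the double knockdown score for 240 density-responsive raised transcripts (50.0% to 55.2% in the 2 libraries) and 35.6% for 188 density-flat ones. It was 27.8% for 441 density-responsive lowered transcripts and -3.31% for 314 density-flat ones. The smaller of the differences was 17.0 percentage points, above 0 with each double knockdown library alone as the reference (8.10 to 24.4 points for the raised set and 26.6 to 35.8 for the lowered one). These shares are the part moved by YAP5SA only if the cells lacked the shRNAs. If they held both, as another label says, the share is the knockdown effect left over and the part moved is the rest: 47.4% of the density-responsive and 64.4% of the density-flat raised transcripts' score, and 72.2% and 103% for the lowered ones, the opposite order. With density response taken from the single knockdown cells the shares were 54.2% against 31.0% and 25.1% against 0.575%, or turned, 45.8% against 69.0% and 74.9% against 99.4%. The hypothesis stays open, since the conflict in the labels decides the direction.

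A second hypothesis was that YAP5SA+S94A expression removes more of the knockdown response among transcripts that do not follow density. S94A libraries lacked 52.6% of the double knockdown score of the density-flat raised transcripts and 44.4% of that of the density-responsive ones, and 54.8% and 39.3% for the lowered transcripts. The smaller difference was 8.26 percentage points. With each double knockdown library alone as the reference it ran from -5.77 to 16.7 points for the raised set, above 0 in 8 of 9 pairs of libraries, and from 8.13 to 22.3 for the lowered set. With density response taken from the single knockdown cells, the density-flat and density-responsive shares were 50.9% and 38.9% (raised) and 54.8% and 37.6% (lowered). The differences then ran from -2.8 to 24.3 points for the raised set, above 0 in 8 of 9 pairs, and from 9.92 to 24.5 for the lowered set. The hypothesis stays open, since the order for the raised set was not beyond the spread of the libraries. A weaker knockdown in that line was not tested, because the targeted transcripts could not be identified.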
